A study of Mus musculus with 6 samples.

How the data were processed

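RNA-seq was measured in 6 samples of the mouse line TC-1, 3 untreated and 3 treated with 20 ng/ml murine IFN-gamma for 72 h. Per the labels, RNA was extracted with TRIzol, and 2 library kits are named for every sample, a stranded kit after poly(A) selection and a kit that reads the 3' ends of mRNA. The labels do not say which kit gave these counts, so changes were tested between groups for each gene. The myeloid check sets levels of different genes side by side without a correction for length. It rests on Mpeg1 being 127 times the highest of the 11 markers other than Mpeg1, Cd68 and Cd14. The submitters' processing notes list Bowtie2 and edgeR, with no version, and hg19, a human build, for mouse samples. In the table, 23152 of 23238 distinct symbols (99.6%) matched mouse reference tables (GRCm38.p6 and GENCODE), so the rows were read as mouse genes and no coordinates were used.

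The table deposited by the authors held raw counts per gene and log2 normalized values for the 6 samples. The counts deposited by the authors were whole numbers with no normalization. The log2 values deposited by the authors matched log2 of edgeR's TMM-scaled pseudo-counts plus 1, computed here from the counts with no groups, to within 0.00493. No value column was left unused. Of 23282 rows, 6464 had 0 counts in all 6 libraries, and 79 rows carried a symbol that stands on more than 1 row and were kept apart. Among rows with at least 600 counts, 6 had counts equal to those of another row in every library, so reads were counted on both of such overlapping or duplicate genes. Such genes, and near-identical family members, are uncertain. The ribosomal precursor row Rn45s held between 5.81% and 9.69% of the counts of a library. Genes with processed pseudogene copies, among them Eno1 and Gapdh of the glycolysis list and keratin genes, may have lost reads that matched several places.

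Samples were grouped by the treatment label. All pairs of libraries differed by more than sampling noise, so none was treated as a duplicate. On log2 CPM (prior count 2) the first principal component held 63.9% of the variance and separated the groups.

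Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood fit, Benjamini-Hochberg adjustment, threshold 0.05), with no covariate. The filter left 12191 genes and the biological coefficient of variation was 0.0871. The standard error was taken from the log2 fold change and the F statistic. For genes with a deviating library the robust fit uses fewer degrees of freedom, so p is larger than the standard error alone would give. Gene lists were tested two-sided with camera on voom values in limma 3.58.1 (correlation between genes preset at 0.01), adjusted over the 21 lists with at least 5 tested members out of 25. The test was repeated with the correlation estimated, and with fry, which tests a list's genes alone. With an estimated correlation 7 of the 15 calls held: MHC class I, receptor and JAK-STAT, GTPases, antiviral genes, chemokines, checkpoint genes and NF-kappaB targets.

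The design, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 highest and 8 lowest log2 fold changes among genes past the threshold, with a mean of at least 10 CPM and groups that did not overlap. From each list it took the 2 smallest adjusted p, the highest CPM and the largest change against the list's majority. Irf1, Ifngr1, Ifngr2, Socs1, Cd274, Ciita, B2m, H2-K1, H2-D1, Cdkn1a and Mki67 were always named. Some genes that the rule or a count would name are not reported here. Other genes, named to complete a count of 5 or fewer or as single values (such as Cxcl9, Slc7a11, Ido1, Krt7, Krt8, Epcam and Cdh1), were chosen after their values were seen.

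A fold against a group with 0 counts was computed against a floor of 3 counts over the group, with the treated counts taken as observed. With 1 to 3 counts, the ratio was given with an exact (Clopper-Pearson) 95% interval. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Floors cover only the counting error of the group with 0 counts. At the depths of these libraries, a group at 0 counts allows up to 0.114 CPM (untreated) or 0.107 CPM (IFN-gamma).

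The tests were tested on simulated data drawn from these libraries (12191 genes, 200 changed). edgeR recovered 13 of 50 genes changed by a log2 value of 0.32, 33 of 50 genes changed 1.5-fold, 37 of 50 changed 2-fold and 47 of 50 changed 4-fold, with 7 false calls (5.11% of calls), so many small changes of a size reported here would be missed. Camera called 5 of 5 changed lists and 0 of 20 unchanged ones. The simulated genes were drawn independently of each other, and the changed lists held genes raised 1.5-fold or more. The camera simulation could therefore not test the preset correlation, or list shifts as small as some reported here. The alternatives tried were other scaling factors, other filters, DESeq2 1.42.0, limma voom, limma on the deposited log2 values, a replicate block, thinned counts, a stricter threshold and leaving out each library. Removal of GC and length trends ended the call of a simulated GC-rich list and kept that of a raised list. The motif search recovered a planted motif and found none that held in the genes set aside when the low genes were random. Both of these simulations were redesigned after a first version failed: raised genes had been drawn into the GC-rich list, and the first planted motif was too rare and too weakly enriched to be recovered. Transcript GC content, length and 3' sequence came from GENCODE vM21 transcripts, 1 per symbol, the longest protein-coding one where there was one. Motif and figure scripts used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.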

Results

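The data were RNA-seq gene counts from TC-1 cells, a mouse line that the labels describe as lung adenocarcinoma and that was derived from lung cells transformed with human papillomavirus oncogenes and activated ras. Cells were left untreated (3 libraries) or treated with 20 ng/ml murine interferon-gamma (IFN-gamma), a cytokine made by activated T and NK cells, for 72 h (3 libraries). Total gene counts were 9350991, 7302687 and 9242471 in untreated replicates 1, 2 and 3, and 10861336, 9205802 and 8511379 in IFN-gamma replicates 1, 2 and 3. Of 23282 gene rows, 12191 had enough counts to be tested. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Levels are given as CPM, counts scaled to 1e6 per library, as mean ± SD with n = 3 libraries per group, changes as log2 fold change ± standard error (IFN-gamma over untreated), and adjusted p-values come from edgeR for genes and from camera for gene lists. No coordinates are given because the submitters' notes name no mouse genome build.

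In TC-1 cells treated with IFN-gamma, against untreated cells, interferon-inducible GTPases, antiviral genes and MHC class I presentation genes rose together, most of them by over 4-fold, while some matrix genes, most of the glycolytic enzymes tested and some cell cycle genes were modestly lower. The list calls of the matrix, glycolysis, S phase and mitosis genes were lost with an estimated correlation (adjusted p from 0.0604 to 0.117 with an estimated correlation). The GTPase Gbp2 went from 17.4 ± 0.78 CPM to 1932 ± 46.6 CPM, and Cd274, which encodes the checkpoint ligand PD-L1, from 4.36 ± 1.4 to 134 ± 22.1 CPM. In the other direction, the collagen gene Col3a1 went from 155 ± 2.4 to 43.7 ± 2.51 CPM. The MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 stayed near the limit of detection in both groups.

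In edgeR's quasi-likelihood test, 1204 genes were higher and 922 lower after IFN-gamma at an adjusted p under 0.05, which is 17.4% of the genes tested. Large changes were mostly increases, with 325 genes at least 2-fold higher and 61 at least 2-fold lower. Genes at least 2-fold higher held 1.18 ± 0.017% of all counts in untreated libraries and 5.06 ± 0.17% in IFN-gamma libraries (SD, n = 3). The groups did not overlap in 95.6% of the changed genes, against 31.8% of all tested genes and 10% by chance. The split between directions depended on the scaling. With upper-quartile factors 957 genes were higher and 1343 lower, and with total counts alone 991 were higher and 1238 lower, so that 41.6% and 44.5% of the changed genes were higher, against 56.6% with TMM factors.

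**Figure D1:**
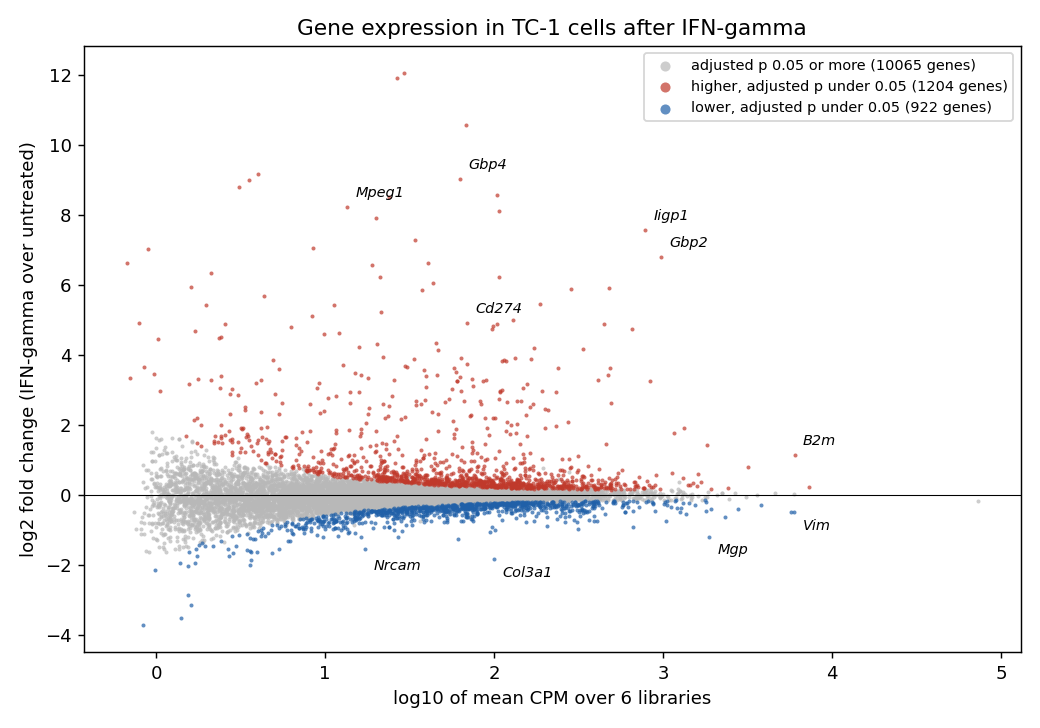
Each point is 1 of the 12191 tested genes, with the log10 of its mean CPM over the 6 libraries on the x axis and its log2 fold change (IFN-gamma over untreated) on the y axis. The 1204 genes called higher reach much larger changes than the 922 called lower, of which Col3a1 (-1.83) has the lowest value among well-expressed genes.

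The genes with the highest fold changes among those of at least 10 CPM were nearly silent in untreated cells. Serpina3f, a serpin, had 0 counts in the untreated group and 58.4 ± 5.63 CPM after IFN-gamma, at least 509-fold higher against a floor of 3 counts over the group. Batf2, a transcription factor of the AP-1 family, also had 0 untreated counts and reached 53.5 ± 3.58 CPM, at least 471-fold higher. Gm12250 had 2 untreated counts and 136 ± 5.97 CPM after treatment, a ratio of 1779 with an exact 95% interval of 492 to 14694. F830016B08Rik had 3 untreated counts and a ratio of 410, with an interval of 140 to 1991. Mpeg1, a pore-forming protein gene best known from macrophages, had 2 untreated counts and 27.0 ± 1.9 CPM after treatment, a ratio of 356 with an interval of 98.1 to 2942. All untreated counts of Gm12250 and F830016B08Rik came from untreated replicate 3, without which these genes were at least 754-fold and 261-fold higher. Those of Mpeg1 came from untreated replicate 1, without which it was at least 153-fold higher. These intervals cover counting error only. The GTPase gene Gbp4 had 6 untreated counts, 5 of them in untreated replicate 1, and a ratio of 553 with an interval of 254 to 1509. Without that library the ratio was 2140, with an interval of 384 to 84531. Its log2 fold change was 9.02 ± 0.22 and ranged from 8.57 to 10.75 in the fits without 1 library. The GTPase genes Tgtp1 (8.56 ± 0.16) and Tgtp2 (8.11 ± 0.16) completed the 8 highest, all at an adjusted p of at most 3.1e-21. Tgtp1 and Tgtp2 are near-identical copies, so the division of reads between them is uncertain.

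Of the 8 genes of at least 10 CPM with the lowest fold changes, Col3a1 fell by 1.83 ± 0.08 (adjusted p = 7.7e-22), and Mgp, the matrix Gla protein, by 1.19 ± 0.05 from 2600 ± 24 to 1136 ± 10.1 CPM (adjusted p = 5.5e-23). The neuronal adhesion gene Nrcam fell by 1.55 ± 0.17, the neuronal pentraxin Nptx1 by 1.27 ± 0.10, the vesicular glutamate transporter Slc17a6 by 1.21 ± 0.14 and the proenkephalin gene Penk by 1.08 ± 0.17. The transcriptional inhibitor Id2 fell by 1.18 ± 0.17 and Selenbp1 by 1.17 ± 0.20. The adjusted p of these 8 genes was at most 1.6e-05.

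Genes of the interferon-gamma receptor and JAK-STAT list rose, with 8 of 11 tested members higher and 0 lower (8 and 0 adjusted over the list alone; list adjusted p = 1.18e-15, and adjusted p = 0.013 with an estimated correlation). Irf1, an interferon-induced transcription factor, rose by 3.62 ± 0.07 to 900 ± 18.8 CPM. The 3 members that did not pass were Jak1 and both receptor chains, Ifngr1 (-0.11 ± 0.11, adjusted p = 0.57) and Ifngr2 (0.02 ± 0.12, adjusted p = 0.95). Of 11 negative regulators of JAK-STAT signalling, 4 were higher and 1 lower (5 and 1 adjusted over the list alone; list adjusted p = 0.00946, and adjusted p = 0.080 with an estimated correlation). Usp18, an ISG15 protease, rose by 3.38 ± 0.12, Socs1 by 1.56 ± 0.14, Socs3 by 0.47 ± 0.07 and the phosphatase gene Ptpn11 by 0.43 ± 0.07. Socs2 was lower by -0.36 ± 0.10 (adjusted p = 0.0099), a call lost without untreated replicate 3 (adjusted p = 0.0528) or IFN-gamma replicate 2 (adjusted p = 0.0586).

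All 18 tested interferon-inducible GTPases were higher (18 adjusted over the list alone), with a median log2 fold change of 6.15, or 5.91 with the 2 members that had no untreated counts set at their lower bounds. The list adjusted p was 3.87e-51, and the adjusted p was 0.00838 with an estimated correlation. Gbp2 rose by 6.79 ± 0.07 and Iigp1, an immunity-related GTPase that acts on pathogen vacuoles, by 7.57 ± 0.09 to 1562 ± 14.6 CPM. Reads of the related genes Gbp6 and Gbp10 may have been divided between them. Of 35 antiviral interferon-stimulated genes, 34 were higher and 0 lower (35 and 0 adjusted over the list alone), with a median of 3.07 (list adjusted p = 7.99e-82, and adjusted p = 0.00578 with an estimated correlation). Ifi44 rose by 4.89 ± 0.07 and Ifit3, an RNA-binding antiviral effector, by 4.75 ± 0.07 to 1260 ± 54 CPM. The member that did not pass over all genes was Tmem173, which encodes STING (0.24 ± 0.10, adjusted p = 0.096).

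**Figure D2:**
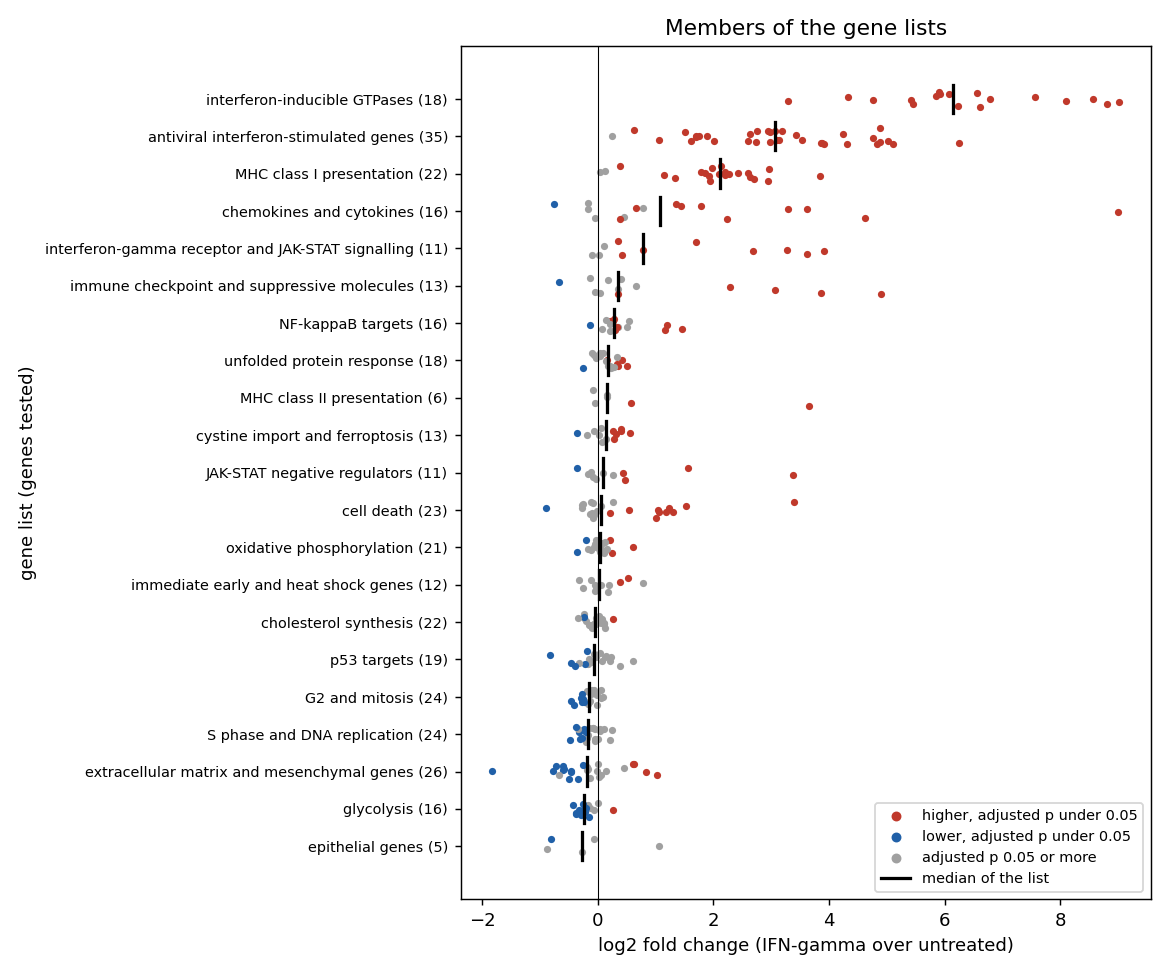
Points are the tested members of each gene list (y axis, with the number tested), placed by log2 fold change on the x axis and coloured by call, and black bars are list medians. The 18 GTPases lie at 3.29 or more, whereas the S phase, mitosis, glycolysis and matrix lists have medians between -0.24 and -0.15.

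MHC class I presentation genes rose from the antigen-processing proteasome to the surface molecules. Of 22 tested members, 20 were higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 2.11 (list adjusted p = 2.78e-45, and adjusted p = 0.00199 with an estimated correlation). The immunoproteasome subunit genes Psmb10 and Psmb8 rose by 3.85 ± 0.09 and 2.95 ± 0.07. The heavy chain genes H2-K1 and H2-D1 rose by 1.91 ± 0.05 and 1.78 ± 0.05, to 2098 ± 54 and 1797 ± 95 CPM, although class I genes resemble each other closely and the division of reads among them is uncertain. B2m, the shared light chain, rose by 1.14 ± 0.05 to 8261 ± 397 CPM. The chaperone genes Canx and Pdia3 did not pass, with 0.04 ± 0.06 and 0.12 ± 0.06, although Pdia3 passed without IFN-gamma replicate 1 (adjusted p = 0.049).

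MHC class II genes were too scarce for most of them to be tested. Of 14 members 6 were tested, of which 2 were higher (2 adjusted over the list alone), and the list did not pass (adjusted p = 0.148, and adjusted p = 0.329 with an estimated correlation). Ciita, the transcriptional master regulator of class II genes, had 0 counts in each untreated library and 8, 4 and 4 counts in IFN-gamma replicates 1, 2 and 3. Against the floor of 3 counts over the group this is 4.98-fold higher, which leaves out the counting error of the treated libraries. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had between 0 and 3 counts in every library, and a group at 0 counts allows up to 0.114 CPM in untreated and 0.107 CPM in IFN-gamma libraries. Summed with Ciita, these genes had 4 counts in untreated and 29 in IFN-gamma libraries, and 16 of the 29 were counts of Ciita. H2-DMb1 lay well above the limit, with 427 untreated and 504 IFN-gamma counts (ratio 1.10, exact 95% interval 0.967 to 1.26). The 2 members that rose were Rfx5, a promoter-binding factor (0.58 ± 0.11, adjusted p = 0.0002), and the lysosomal protease gene Ctss, which had 3 untreated and 44 IFN-gamma counts (ratio 13.7, exact 95% interval 4.39 to 68.9). Without untreated replicate 3 the Ctss ratio was 26.1, with an interval of 4.45 to 1055. It was 9.85 without untreated replicate 2 (interval 3.16 to 49.6) and 13.2 without untreated replicate 1 (interval 3.45 to 113).

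Of 16 chemokine and cytokine genes, 10 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median of 1.07 (list adjusted p = 7.30e-10, and adjusted p = 0.0125 with an estimated correlation). The monocyte chemoattractant genes Ccl7 and Ccl2 rose by 2.23 ± 0.14 and 1.44 ± 0.17, the latter from 978 ± 39 to 2664 ± 526 CPM (adjusted p = 0.0066). Cxcl9, a T cell chemoattractant, had 0 untreated counts and 7.08 CPM after treatment, at least 61.6-fold higher. The alarmin gene Il33 fell by 0.76 ± 0.06 (adjusted p = 1.5e-13). Of 13 immune checkpoint and suppressive genes, 5 were higher and 1 lower (6 and 1 adjusted over the list alone; list adjusted p = 0.00013, and adjusted p = 0.0392 with an estimated correlation). Cd274 rose by 4.91 ± 0.16, Nos2 by 3.87 ± 0.41, Ido2 by 3.06 ± 0.50, the galectin gene Lgals9 by 2.29 ± 0.09 and Pvrl2 by 0.35 ± 0.10, while Ceacam1 fell by 0.67 ± 0.14. The Pvrl2 call was lost without untreated replicate 3 (adjusted p = 0.0517) or IFN-gamma replicate 2 (adjusted p = 0.0588). Ido1, a tryptophan-degrading enzyme that IFN-gamma induces in many cells, had 0 counts in all 6 libraries. Cd47, a signal against phagocytosis, did not pass (0.03 ± 0.30, adjusted p = 0.97), but IFN-gamma replicate 2 stood apart with 233 CPM against 470 and 458 CPM in the other IFN-gamma libraries and 386, 373 and 380 CPM in the untreated ones. Without that library Cd47 was higher by 0.29 (adjusted p = 0.000206).

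**Figure D3:**
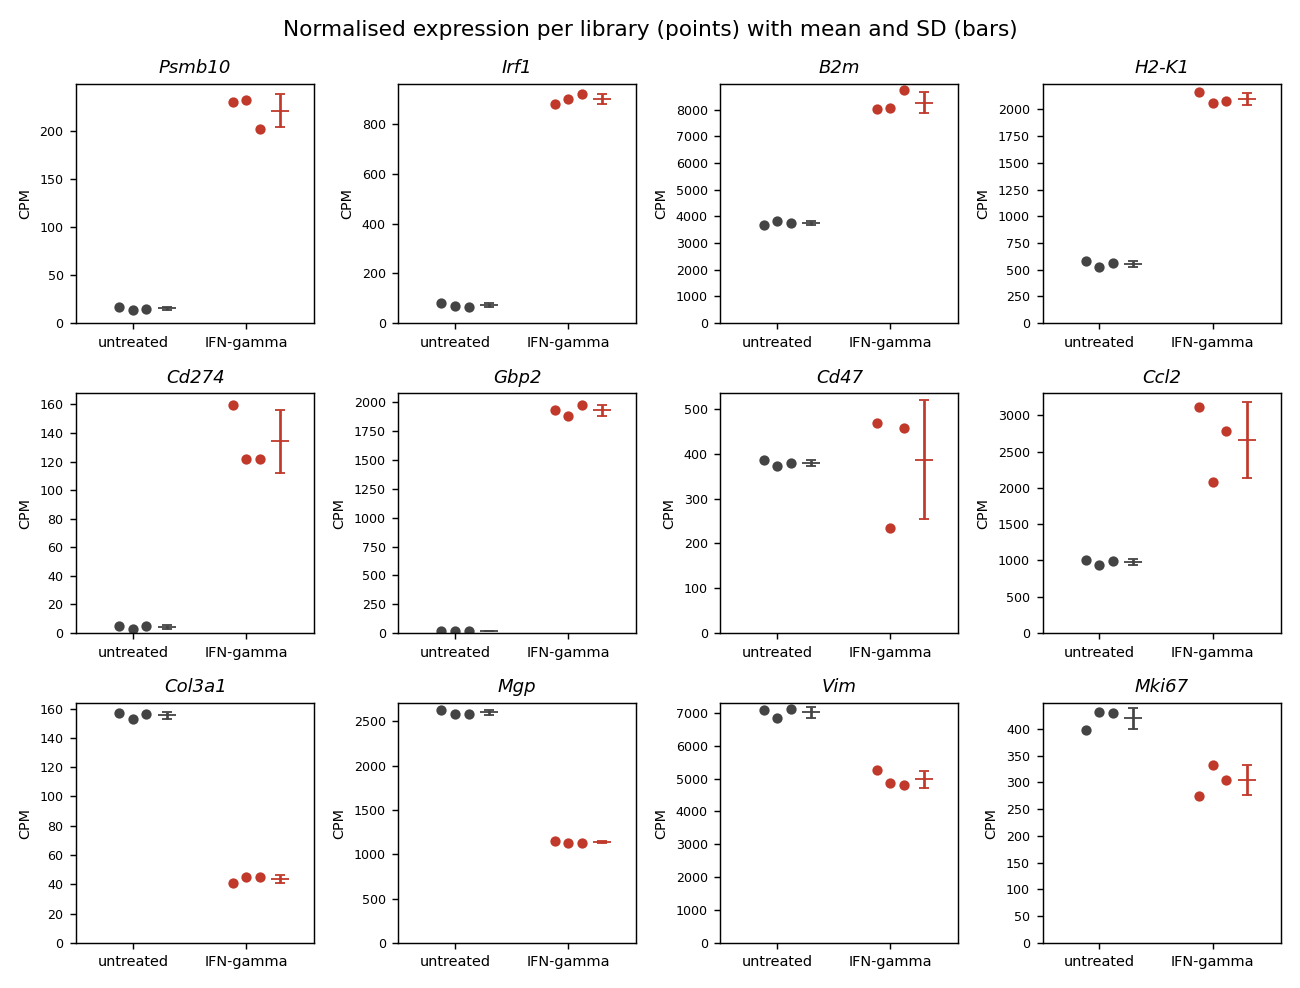
Each panel shows the CPM of a gene (y axis, from 0) in the 3 untreated and 3 IFN-gamma libraries as points, with mean and SD as bars. The groups are apart for the genes shown except Cd47, where IFN-gamma replicate 2 lies at 233 CPM, below all other libraries.

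Of 16 targets of NF-kappaB, 8 were higher and 1 lower (10 and 1 adjusted over the list alone; list adjusted p = 3.89e-06, and adjusted p = 0.0331 with an estimated correlation). The adhesion molecule gene Vcam1 rose by 1.46 ± 0.08 and the mitochondrial superoxide dismutase gene Sod2 by 1.19 ± 0.07. Ier3 was lower by -0.15 ± 0.05 (adjusted p = 0.033), a call lost in the fits without untreated replicates 1, 2 or 3 or IFN-gamma replicates 1 or 2 and with no filter on low counts (adjusted p from 0.0527 to 0.161). Of 23 cell death genes, 10 were higher and 1 lower (10 and 2 adjusted over the list alone; list adjusted p = 0.00163, and adjusted p = 0.061 with an estimated correlation). The median was only 0.05, against -0.02 without untreated replicate 1, 0.13 without untreated replicate 2, 0.10 without untreated replicate 3 or IFN-gamma replicate 1, 0.02 with thinned counts, 0.00 with total counts alone and -0.01 with upper-quartile factors. The members that rose included Mlkl (1.29 ± 0.09), the effector of necroptosis, and Gsdmd (1.17 ± 0.11), the effector of pyroptosis. The survival gene Mcl1 had -0.08 ± 0.06. The gasdermin E gene, listed as Dfna5, was lower by -0.90 ± 0.26, a call lost without untreated replicate 3 (adjusted p = 0.07) or IFN-gamma replicate 3 (adjusted p = 0.0521). Without IFN-gamma replicate 1 or 2, or with upper-quartile factors or total counts alone, 2 members were lower.

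Of 13 genes of cystine import and ferroptosis, 6 were higher and 1 lower (7 and 1 adjusted over the list alone). The list adjusted p was 0.0291, and the call was lost with an estimated correlation (adjusted p = 0.106), with upper-quartile factors (adjusted p = 0.0666) and with total counts alone (adjusted p = 0.0692). Acsl4, which activates polyunsaturated fatty acids for use in lipids, rose by 0.40 ± 0.06. The ferritin gene Fth1 rose by 0.26 ± 0.05 and the cystine transporter gene Slc7a11 by 0.32 ± 0.08, while the transferrin receptor gene Tfrc fell by 0.36 ± 0.09. Of 18 unfolded protein response genes, 5 were higher and 1 lower (7 and 1 adjusted over the list alone; list adjusted p = 0.00857, and adjusted p = 0.0767 with an estimated correlation). The chaperone gene Hspa5 rose by 0.50 ± 0.05, and Chac1, Manf and Dnajc3 by 0.34 to 0.42. Pdia6 was higher by 0.15 ± 0.05, a call lost with upper-quartile factors (adjusted p = 0.218) or total counts alone (adjusted p = 0.213), with no filter or thinned counts (adjusted p = 0.0533 and 0.0522) and without untreated replicate 1, 2 or 3 or IFN-gamma replicate 1 or 2 (adjusted p from 0.0509 to 0.159). Herpud1 was lower by -0.26 ± 0.09 (adjusted p = 0.046), a call lost in each fit that left out untreated replicate 1, 2 or 3 or IFN-gamma replicate 1 or 2 (adjusted p from 0.0616 to 0.189), with no filter, with DESeq2 and with limma on the deposited log2 values (adjusted p from 0.0538 to 0.0733).

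Genes of extracellular matrix and mesenchymal cells were lower as a list, with 11 of 26 tested members lower and 4 higher (14 and 4 adjusted over the list alone; list adjusted p = 4.40e-05, and adjusted p = 0.0767 with an estimated correlation). Besides Col3a1, the intermediate filament gene Vim fell by 0.49 ± 0.05 from 7015 ± 158 to 4979 ± 250 CPM. Members that rose included Thbs1 (1.03 ± 0.07), Ctgf (0.82 ± 0.13) and Acta2 (0.60 ± 0.12). Epithelial genes were scarce in both groups: 5 of 20 were tested, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.374, and adjusted p = 0.448 with an estimated correlation). The keratin gene Krt19 fell by 0.81 ± 0.20 from 14.1 ± 2.1 CPM, Tjp1 had -0.07 ± 0.09 and Muc1 1.06 ± 0.54 (adjusted p = 0.19). Krt8 had -0.88 ± 0.65 (adjusted p = 0.405), and of members not tested Krt7 had 32 counts in the untreated group and 6 in the treated group, Cdh1 9 and 8 and Epcam 2 and 0.

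Cell cycle lists were lower by small amounts. Of 24 S phase genes, 8 were lower and 0 higher (10 and 1 adjusted over the list alone; list adjusted p = 0.00146, and adjusted p = 0.0604 with an estimated correlation), with a median of -0.16. Without untreated replicate 2 or 3, 5 of them were lower, and without IFN-gamma replicate 2, 1 was higher. Of 24 G2 and mitosis genes, 8 were lower and 0 higher (8 and 0 adjusted over the list alone; list adjusted p = 0.00013, and adjusted p = 0.0843 with an estimated correlation), with a median of -0.15. Without untreated replicate 2 or IFN-gamma replicate 1 or 2, 5 of them were lower. The proliferation marker Mki67 fell by 0.47 ± 0.06 from 420 ± 20 to 304 ± 28.5 CPM, the spindle gene Nusap1 by 0.41 ± 0.06, the transcription factor E2f1 by 0.38 ± 0.07 and the ribonucleotide reductase gene Rrm1 by 0.32 ± 0.07. Top2a had 0.04 ± 0.05. The helicase gene Mcm7 was lower by -0.24 ± 0.06 (adjusted p = 0.0027), a call lost without IFN-gamma replicate 1 (adjusted p = 0.0567). Of 19 p53 targets, 5 were lower and 0 higher (5 and 0 adjusted over the list alone), and the list did not pass (adjusted p = 0.214, and adjusted p = 0.28 with an estimated correlation). The 5 became 2 without untreated replicate 2 or IFN-gamma replicate 1, and 3 without untreated replicate 3 or IFN-gamma replicate 2, and 1 other was higher without IFN-gamma replicate 3. The 5 were Zmat3 (-0.39 ± 0.07), Trp53inp1 (-0.47 ± 0.12), Perp (-0.83 ± 0.27), Ccng1 (-0.19 ± 0.07) and Cdkn1a, the cell cycle inhibitor p21 (-0.22 ± 0.06). The Trp53inp1 call was lost without untreated replicate 2 (adjusted p = 0.0734), and the Cdkn1a call without untreated replicate 3 (adjusted p = 0.0732) or IFN-gamma replicate 1 (adjusted p = 0.0509). The Perp call was lost without untreated replicate 1 or 2 or IFN-gamma replicate 1 or 2 (adjusted p from 0.0821 to 0.0984) and with DESeq2 (adjusted p = 0.0574). The Ccng1 call was lost in every fit without 1 library except untreated replicate 1 (adjusted p from 0.0703 to 0.252), and with no filter, DESeq2, limma voom or limma on the deposited log2 values (adjusted p from 0.0539 to 0.0697).

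Of 16 glycolysis genes, 11 were lower and 1 higher (11 and 1 adjusted over the list alone; list adjusted p = 2.02e-06, and adjusted p = 0.117 with an estimated correlation), with a median of -0.24. Pdk1, which restrains pyruvate oxidation, fell by 0.43 ± 0.07, Gpi1 by 0.37 ± 0.06 and Pkm by 0.20 ± 0.05 from 1932 ± 53 to 1678 ± 15.6 CPM. Hk2, a hexokinase, rose by 0.26 ± 0.06. Oxidative phosphorylation genes did not pass as a list (adjusted p = 0.526, and adjusted p = 0.712 with an estimated correlation), with 3 of 21 higher and 2 lower (4 and 2 adjusted over the list alone), which became 1 higher and 3 lower with upper-quartile factors. Cycs (0.61 ± 0.09), Sdhb (0.24 ± 0.07) and Cox5a (0.21 ± 0.07) were higher, but with upper-quartile factors or total counts alone Sdhb (adjusted p = 0.0674 and 0.0577) and Cox5a (adjusted p = 0.139 and 0.134) did not pass. Sdhb was also lost without untreated replicate 3 or IFN-gamma replicate 2 (adjusted p from 0.0646 to 0.0855), and Cox5a without untreated replicate 1 or 2 or IFN-gamma replicate 2 (adjusted p from 0.158 to 0.196) or with DESeq2 or thinned counts (adjusted p = 0.0678 and 0.0699). Atp5a1 had 0.16 ± 0.06 and passed without IFN-gamma replicate 3 (adjusted p = 0.0014) or with no filter (adjusted p = 0.0478). Cox7a2 (-0.20 ± 0.06) and Ndufa4 (-0.36 ± 0.12) were lower, the first not without untreated replicate 2 or 3 or IFN-gamma replicate 1 (adjusted p from 0.063 to 0.136), the second not without untreated replicate 2 or 3 or IFN-gamma replicate 2 or 3 (adjusted p from 0.0825 to 0.331) or with DESeq2 (adjusted p = 0.104).

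Cholesterol synthesis genes did not pass as a list (adjusted p = 0.355, and adjusted p = 0.618 with an estimated correlation), with 1 of 22 higher and 1 lower (1 and 1 adjusted over the list alone), or 0 higher and 3 lower with upper-quartile factors. These were Sc5d (0.26 ± 0.09) and the regulator Srebf2 (-0.25 ± 0.08), and Msmo1 had -0.03 ± 0.06. The Sc5d call was lost with upper-quartile factors (adjusted p = 0.0828), with total counts alone (adjusted p = 0.0842) and without untreated replicate 1 or 2 or IFN-gamma replicate 1 or 2 (adjusted p from 0.079 to 0.139), and the Srebf2 call in the fits that left out the same libraries (adjusted p from 0.0784 to 0.249) and with DESeq2 (adjusted p = 0.0691). Immediate early and heat shock genes, which respond to handling, did not pass either (adjusted p = 0.4, and adjusted p = 0.661 with an estimated correlation), with 2 of 12 higher and 0 lower (4 and 0 adjusted over the list alone). Hsph1 had 0.39 ± 0.09 and Atf3 0.52 ± 0.15, the latter not past the threshold without untreated replicate 2 (adjusted p = 0.0511) or IFN-gamma replicate 1 (adjusted p = 0.102). Without IFN-gamma replicate 2, 4 of the 12 were higher, and without IFN-gamma replicate 3, 1 was lower. Egr1 had -0.03 ± 0.05.

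Of 14 myeloid markers, 3 were tested and 2 were higher (2 adjusted over the list alone): Mpeg1 and Cd68, a lysosomal protein gene (0.73 ± 0.23, adjusted p = 0.023), whose call was lost without untreated replicate 1 or 2 or IFN-gamma replicate 2 (adjusted p from 0.0615 to 0.156), with DESeq2 (adjusted p = 0.0586) or with thinned counts (adjusted p = 0.0646). Cd14 had 0.05 ± 0.12, at 37.9 ± 4.34 and 39.4 ± 6.53 CPM. The other 11 markers had 18 counts in all untreated and 16 in all IFN-gamma libraries. None of the 14 lymphocyte markers measured had enough counts to be tested. Of 12 endothelial markers, 4 were tested and 1, the receptor gene Flt1 at 115 ± 8.99 and 98.5 ± 9.44 CPM, was lower (-0.23 ± 0.08, adjusted p = 0.0492; 1 adjusted over the list alone), which did not hold without untreated replicate 2 or 3 or IFN-gamma replicate 1 (adjusted p from 0.116 to 0.331). It was also lost with DESeq2, DESeq2 size factors, thinned counts, limma on the deposited log2 values or Rn45s left out (adjusted p from 0.0505 to 0.108). Egfl7 had -0.17 ± 0.16, at 18.5 ± 1.07 and 16.4 ± 1.94 CPM. The mitochondrially encoded genes had no rows in the table and were not analysed here.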

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

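Leaving out Rn45s, and upper-quartile factors and total counts for the lists, were chosen after seeing the data. The counts of genes higher (838 to 1298 over all alternatives) and at least 2-fold higher (305 to 343) stayed within 1.5 times their values. Genes lower ranged from 654 to 1343 and genes at least 2-fold lower from 56 to 84 except at an adjusted p under 0.01, where 528 were lower and 37 at least 2-fold lower, as a stricter threshold must give fewer. DESeq2 called 1770 genes, of which 1744 were among the 2126 of edgeR, and no shared call changed sign in any alternative. Upper-quartile factors and total counts kept 1879 and 1913 of the 2126 calls. The labels do not say whether replicate numbers pair the samples. Over well-expressed genes no such pairing was seen (correlations of same-numbered deviations 0.022, 0.076 and -0.0008), which does not exclude pairing in some genes. A fit with the replicate block gave 1252 genes higher and 974 lower, with 15 lists past the threshold.

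Of 21 lists, 15 passed with the preset correlation and 7 with the estimated one, which allows for genes that move together. The calls lost had an adjusted p of 0.061 (cell death), 0.106 (ferroptosis), 0.0767 (matrix), 0.0843 (G2 and mitosis), 0.117 (glycolysis), 0.08 (negative regulators), 0.0604 (S phase) and 0.0767 (unfolded protein response). The ferroptosis list was also lost with upper-quartile factors (0.0666) and total counts (0.0692), and the cause was not tested. With fry the class II (0.0331), epithelial (0.0342) and p53 (0.0342) lists passed as well. Fry does not compare a list with other genes, but whether that is why they passed was not tested. All 15 list calls held in the fits without 1 library. No gene stood in more than 1 list, so leaving out shared genes changed nothing.

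Of 1799 values of 106 genes that the rule or the text names, 1681 kept direction and side of the threshold, 93 lost and 5 gained a call and 20 changed sign. The sign changes were in 7 genes that did not pass, and the cause was not tested. Cd47 went to -0.024 with upper-quartile factors, -0.011 with total counts, -0.035 with limma voom, -0.028 with the replicate block and -0.036 with limma on the deposited log2 values, and ranged from -0.13 to 0.29 in the fits without 1 library. Ifngr2 went to -0.034 and -0.024 with upper-quartile factors and total counts (-0.052 to 0.13 without 1 library), Cd14 to -0.0017 with upper-quartile factors (-0.067 to 0.16) and Top2a to -0.0063. Canx went to -0.011 and -0.0025 with upper-quartile factors and total counts. Without 1 library, Msmo1 ranged from -0.058 to 0.0070 and Egr1 from -0.051 to 0.0057. Depth limits most class II genes and other genes near 0 counts.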

Other observations

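The search of gene families, the splits of the libraries, the myeloid test, the test of a single deviating library (though not its fits, which were set before the data were examined), the limit of 0.6 log2 units, the motif, its test in the genes it was not picked from and the count of low genes without it were chosen only after the result was seen. Tested genes outside the fixed lists were grouped by the letters of their symbols into 185 families of at least 8 genes, and 5 passed camera, none of them with an estimated correlation (smallest adjusted p = 0.918). Of 62 genes whose symbols begin with Hist, most of them core histone genes, 6 were lower and 0 higher (adjusted p = 0.000507, median -0.30). Of all 12191 tested genes, 922 were lower and 1204 higher. The 6 all have symbols that begin with Hist1h2a, and such close family members may share reads, so they may not be 6 separate changes. Some rows hold equal values, such as Hist2h3c1 and Hist2h3c2 (both -0.403 ± 0.230), so members of this family are not independent. Of 10 Parp genes, which encode ADP-ribosyltransferases, 4 were higher and 0 lower (adjusted p = 0.00235). Genes whose symbols begin with Sox, Tcf or Cdkn were lower as families (adjusted p = 0.0347 each), with 4 of 9, 3 of 10 and 4 of 9 genes lower and 0 higher. They were grouped by letters and not by function. The Cdkn group includes Cdkn2aip and Cdkn2aipnl, which are not inhibitors of cyclin-dependent kinases.

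Refitting the 10 splits of the 6 libraries into 3 and 3, the real split gave 2126 changed genes and 386 changed at least 2-fold, and the highest other split gave 0 and 0 in edgeR. The other 9 splits had 167 to 407 genes at an unadjusted p under 0.05, against 3476 in the real one, and 0 genes with limma voom. For lists the real split gave 15 past the threshold and the other 9 splits 4 to 10, so lists passed where 0 genes were called. In each case 1 of the 10 splits was as large, and 10 splits are too few for a share under 0.05. Each other split also held treated and untreated libraries in both groups, in unequal numbers, so part of the treatment difference stayed between its groups. The lists that passed there are therefore not a level reached by chance alone. The treatment effect also added to the spread within groups, so few gene calls were bound to follow and their number decides nothing.

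Mpeg1 and Cd68, known from macrophages, were higher after IFN-gamma. Macrophages or other myeloid cells among the treated cells would bring their abundant transcripts, such as Lyz2 and Tyrobp. The 11 myeloid markers other than Mpeg1, Cd68 and Cd14 had a median of 0.0355 CPM in treated libraries and a highest value of 0.213 CPM, against 27.1 CPM for Mpeg1, which argues against that source. Expression by the TC-1 cells themselves stays open as a hypothesis, but it was not tested.

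IFN-gamma replicate 2 had 105 of 8981 well-expressed genes more than 0.6 log2 units below the other IFN-gamma libraries, among them Crtc2 (-3.46), Rpa3 (-1.96), Sdhd (-1.75), Cd47 (-0.99) and Tap2 (-0.87), against 19 to 64 in the other 5 libraries. The tables argue against a trend with GC content or length, since the trend in this library was small (SD 0.0177 log2 units) and lay between -0.0396 and 0.0262 in the low genes, against deviations below -0.6, and 101 of the 105 stayed low after each library's trend was taken out. Loss of reads from transcripts with the motif TTATATA in the last 300 bases is a candidate explanation only for the 29 of 105 low genes (27.6%) that held it in the 1 reference transcript searched, and low genes without it numbered 76, against 15 to 61 in the other libraries (exact 95% interval of the ratio to the highest 0.878 to 1.77), so whether it covers the excess of this library stays open. Among 4523 genes not used to pick the motif, 11 of 51 low genes held it against 225 of 4472 others (Fisher's exact odds ratio 5.19, 95% interval 2.37 to 10.5), but scans of all genes had come before, so these genes were not new, and the 236 that held it had a median of only -0.019 log2 units relative to genes matched for GC content, against -0.0163 in untreated replicate 3. Genes of at least 100 and under 300 counts were not examined before, and for them low meant more than 1 log2 unit below. IFN-gamma replicate 2 had 72 such low genes, against 30 to 78 in the other libraries, so it showed no excess among these genes. Of the 72, 5 held the motif against 68 of 1345 others (odds ratio 1.40, interval 0.427 to 3.60), too wide to decide. The odds ratios of the other libraries ranged from 0 in untreated replicate 1 to 2.63 in untreated replicate 3 (interval 0.971 to 6.13). Since the pattern lies in 1 library of a group, no biological explanation was tested.

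The S phase, mitosis, glycolysis and matrix lists were lower by small amounts. After the trend of each library with GC content and length was taken out, the 4 lists kept 81.6% to 103% of their medians and the highest adjusted p was 0.000638, which argues against such a trend as the cause. A single deviating library is argued against by the 6 fits without 1 library, in which the highest adjusted p of the 4 lists was 0.00474. These tests used the preset correlation, and with an estimated one the 4 calls were lost (adjusted p from 0.0604 to 0.117). A slower cycle of treated cells, or cultures of different density after 72 h, may account for the pattern, and both go with the treatment and were not tested.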
